A study of Mus musculus with 12 samples.

How the data were processed

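Poly(A) RNA was sequenced from mouse cardiac fibroblasts in 12 libraries, 3 in each of 4 groups: Smad3 floxed (fl/fl) lean, fl/fl db/db, Smad3 knockout (KO) lean and KO db/db. Per the labels, the mice were C57BL/6 animals of 6 months, and all of them had been given tamoxifen at 100 mg/kg in 2 courses of 5 days, at 8 and at 16 weeks of age. Per the labels, the cells had been sorted as PDGFRa-positive cells lacking CD31 and CD45, surface proteins of endothelial cells and of leukocytes. Libraries were made from poly(A) RNA with a kit that does not mark strand, per the labels. Whether counting used strand is not given in the sources used here.

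The deposited count table held counts, whole numbers of reads per gene and library with no normalization by the authors. The other deposited table held FPKM of the same genes, normalized by the authors to gene length and to a total per library. The submitters' processing notes name CASAVA, TopHat2 2.0, Cufflinks 2.1.1 and HTSeq 0.6.1 and the mouse builds mm10 and GRCm38.p6, without the role or order of each tool. Coordinates are those of the deposited table, on GRCm38. The FPKM were checked against the counts: for every gene with at least 100 counts, FPKM equalled the count divided by gene length and by 1 total per library, with a largest deviation of 0%. These totals were 0.895 to 1.11 times the summed counts, and how the authors scaled them is not given in the sources used here.

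All tests started from the deposited counts. Genes were filtered with filterByExpr on the 4 groups, which kept 15890 of 54532 genes, and libraries were scaled by TMM, with factors between 0.899 and 1.08. A mean per group was fitted to all 12 libraries with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, statmod 1.5.0, and glmQLFTest), with 8 residual degrees of freedom and a common dispersion of 0.17. Benjamini-Hochberg adjusted p-values under 0.05 were called. The 4 simple contrasts were db/db against lean in fl/fl and in KO, and KO against fl/fl in lean and in db/db. The interaction and both effects averaged over the other factor were tested in the same fit. Log2 fold changes carry a standard error (SE) derived from the test, the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, the counts relative to TMM-scaled library totals, given as mean ± SD of 3 libraries.

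Gene lists of 22 pathways and matrix classes held 466 members, of which 451 were tested, and Smad3 was left out of all of them. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 22 lists of a contrast, and again with the correlation estimated per list and with fry. Estimated correlations went up to 0.749. The lists were collagens; collagen processing and crosslinking; matricellular proteins; proteoglycans, elastic fibre and fibronectin; matrix proteases and inhibitors; contractile and myofibroblast genes; TGF-beta family ligands, receptors and Smads; TGF-beta-responsive genes; chemokines, cytokines and NF-kB targets; interferon response; complement; fatty acid oxidation and PPAR targets. The others were lipogenesis and sterol synthesis, insulin, IGF and glucose handling, oxidative phosphorylation, unfolded protein and integrated stress response, antioxidant response, hypoxia and glycolysis, cell cycle, circadian clock, glucocorticoid response, and immediate-early and dissociation stress genes. A further 13 lists held markers of cell types, sex-linked genes and mitochondrially encoded genes. Comparisons, tests, lists and the rule for named genes were fixed before the data were examined.

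Named genes were chosen by that rule. It takes Smad3 and Lepr in every library. Per simple contrast and for the interaction it takes the 6 genes with the largest positive and the 6 with the largest negative log2 fold change that are called, have a symbol and a mean CPM of at least 5, and do not overlap between the libraries compared (a condition not set for the interaction), leaving out predicted genes, pseudogenes and non-coding genes. It also takes, per simple contrast and list, the 3 members with the smallest adjusted p and the 2 with the highest mean CPM, from which the text gives examples, and the 8 genes moved back in the KO with the smallest sum of ranks. With no gene called in a simple contrast, named genes come from the lists and from Smad3 and Lepr. The examples among list members were picked after their values were seen, and those near 0 were mostly passed over. Gpt2, Gria1 and Spock2 lie outside the rule, as do the genes named for the averaged effect of db/db, and were chosen after their values were seen. Of the 40 genes named, 15 overlap another gene of the table in position, and none of those other genes has over 10% of the named gene's counts.

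Library totals lay between 15798672 and 20634299 counts. The filter, TMM and tests were tested on simulated counts of the real genes with 200 changed genes, 100 per fold size. Of genes changed by 4-fold, edgeR recovered 49% in db/db against lean in fl/fl, 62% in KO against fl/fl in db/db, 68% in KO against fl/fl in lean, 62% in db/db against lean in KO and 15% for the interaction. Of genes changed by 2-fold it recovered 5%, 6%, 7%, 2% and 0% in the same order. For the averaged effect of KO it recovered 77% of 4-fold and 38% of 2-fold changes, and for that of db/db 68% and 29%. In these simulations edgeR made 0 to 12 false calls per comparison, voom 0 to 9 and DESeq2 27 to 56. The simulated lists held genes that vary independently, so they say nothing on camera with correlated genes. The simulated libraries were also of equal quality, unlike the real ones, so recovery in the real data may be lower.

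Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE size factors, no filter on low counts, a filter of CPM 1 in 3 libraries, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), the 6 libraries of a contrast alone, a replicate block, and each library left out in turn. Leaving out both libraries that stood apart and adding a covariate of Y-linked transcripts were chosen after seeing the data, as was adjusting list members over the list alone for the averaged effects. No pair of libraries in a group held the same counts, and chi-square divided by its degrees of freedom was 15.5 to 162 between replicates. The 400 regroupings of the exact permutation tests swapped libraries within lean and db/db, or within genotype, and were two-sided. No sample was left out of the main tests.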

Results

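Messenger RNA of sorted cardiac fibroblasts was sequenced in 12 libraries, 3 in each of 4 groups: Smad3 fl/fl lean, Smad3 fl/fl db/db, Smad3 KO lean and Smad3 KO db/db. Smad3 is a transcription factor that carries the TGF-beta signal to the nucleus. The db/db mouse has a defective leptin receptor and becomes obese and diabetic. The title of the series places the comparison in work on TGF-beta signalling of fibroblasts in the diabetic heart. The count table held 54532 genes, of which 15890 were tested, and library totals ranged from 15798672 to 20634299 counts. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries. In each group the libraries differed in Xist or Y-linked transcripts, so not all 3 came from the same animal or pool, while 2 of them still could.

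Smad3 (chromosome 9, 63646767 to 63757994) was not counted lower in the KO libraries. Its level was 150 ± 18.7 CPM (SD, n = 3) in fl/fl lean, 148 ± 14.8 in fl/fl db/db, 169 ± 14.0 in KO lean and 215 ± 41.2 in KO db/db. The KO libraries lay higher by 0.34 on the log2 scale (exact permutation test within lean and within db/db, two-sided p = 0.02 over 400 regroupings, the smallest possible being 0.005). The edgeR p-value, adjusted over Smad3 and Lepr, was 0.0255, and Smad3 was not called over all genes. The lean groups overlapped, at 156 to 184 CPM in KO and 134 to 171 in fl/fl. The highest library was KO db/db 3, at 254 CPM. A count over the whole gene also takes in exons that a floxed allele keeps, so it does not check the deletion. The groups are therefore called KO-labelled below, and directions drawn from them rest on the labels. Lepr, the leptin receptor gene (chromosome 4, 101717404 to 101815352), was lower in all 6 db/db libraries than in any of the 6 lean libraries. Its level was 87.7 ± 18.3 CPM in fl/fl lean, 37.3 ± 4.0 in fl/fl db/db, 104 ± 17.1 in KO-labelled lean and 39.1 ± 12.8 in KO-labelled db/db. The averaged log2 fold change was -1.32 (SE 0.18; edgeR adjusted p = 0.0562 over all genes and 1.42e-05 over the 2 genes fixed in advance). The exact permutation test gave p = 0.005, the smallest it can give. This count does not read the mutation itself.

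**Figure D1:**
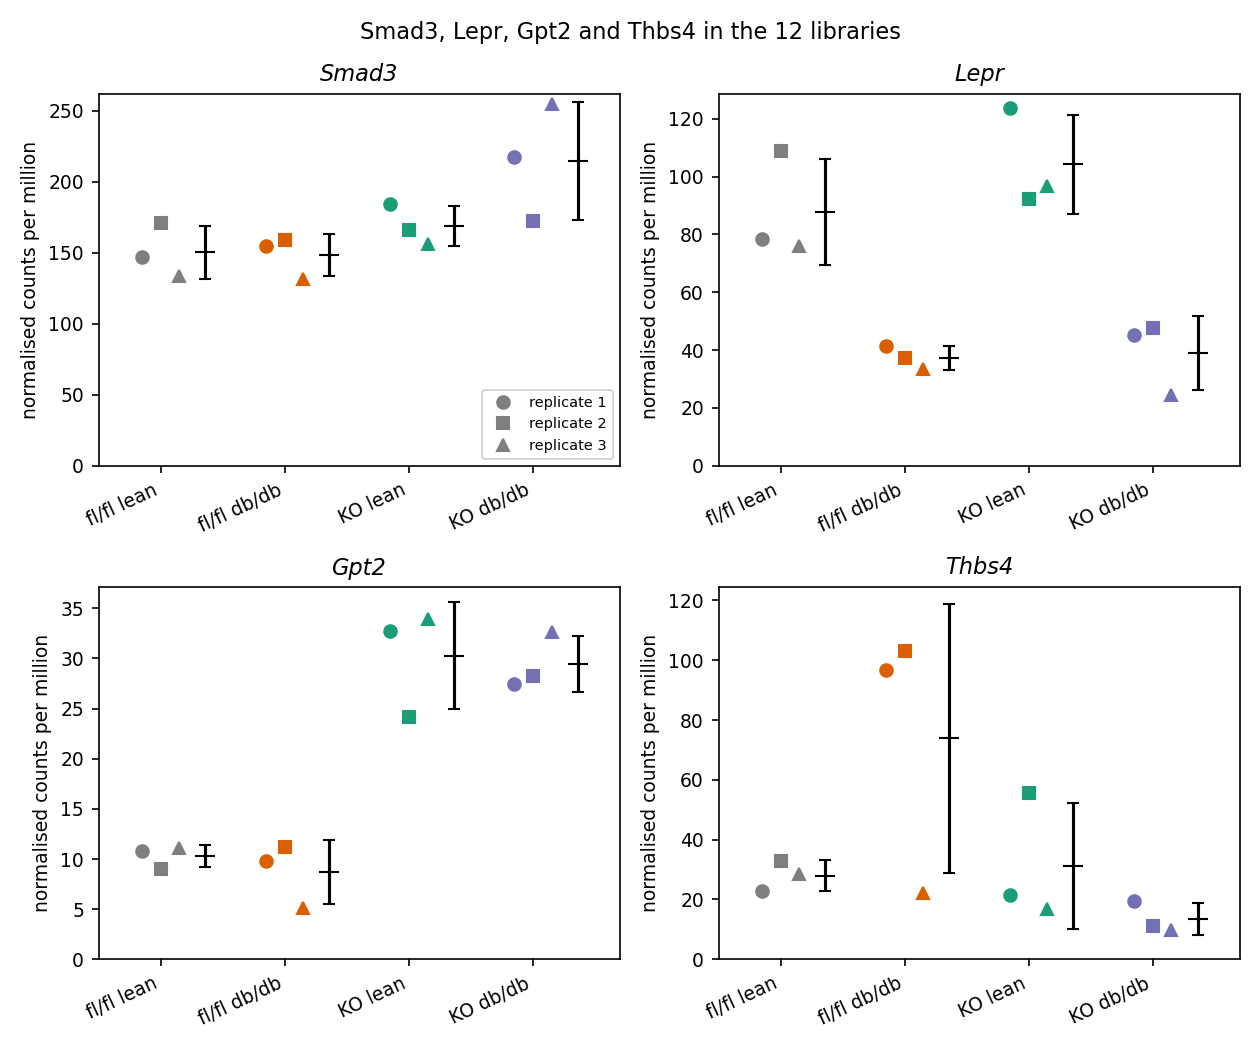
Normalised counts (CPM) of Smad3, Lepr, Gpt2 and Thbs4 in the 12 libraries, by group, with the mean and SD of 3 libraries as a bar beside the points and replicate numbers as symbols. Lepr lies between 24.3 and 47.6 in db/db and between 75.9 and 124 in lean libraries, and Gpt2 between 24.2 and 33.9 in KO-labelled and between 5.15 and 11.2 in fl/fl libraries.

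The libraries were mostly fibroblast RNA. The 10 fibroblast markers summed to between 68506 and 104780 CPM per library, against at most 17.6 CPM for 12 macrophage and monocyte markers and at most 3.34 CPM for 8 lymphocyte markers. The 12 endothelial markers summed to between 283 and 497 CPM, where the sort on CD31 and CD45 would remove endothelial cells and leukocytes. Their mean log2(CPM + 1) was only 2.05 to 2.76, so the sum came unevenly from the 12 markers. It is not a measure of remaining endothelial cells. The 10 pericyte and smooth muscle markers summed to 504 to 693 CPM, the 7 Schwann and neural markers to 30.4 to 102 CPM, and the 9 adipocyte markers to 14.6 to 36.4 CPM. Some libraries held more of another type. The 8 epicardial and mesothelial markers summed to 220 CPM in KO lean 2 and 64.3 CPM in fl/fl lean 2, against a median of 5.05 CPM. The 16 cardiomyocyte markers summed to 65.9 CPM in KO db/db 3 and at most 32.0 CPM elsewhere, and the 6 erythroid markers to 343 CPM in KO db/db 2 and at most 119 CPM elsewhere. The 9 mitochondrially encoded genes summed to 20249 CPM in KO lean 2 and 18123 CPM in fl/fl lean 2, and to between 10266 and 13521 CPM elsewhere.

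Libraries fl/fl lean 3 and KO db/db 3 stood apart from the other 10 on the first principal component, which held 33.1% of the variance. Their scores were 94.2 and 105.3, against -57.8 to 14.3 for the others. They had 16416 and 17531 genes with at least 1 count, against 18653 to 21423 elsewhere, although their totals of 18537390 and 18887031 counts lay within the range of the other libraries. Long genes were counted lower in both, with correlations of gene deviation with gene length of -0.272 and -0.254 across genes, against -0.073 to 0.204 elsewhere. Xist, expressed from the inactive X chromosome of females, and 4 Y-linked genes were both above 5 CPM in 4 libraries, all lean (fl/fl lean 1 and 3, KO lean 1 and 2). Of the other libraries, 5 held Xist alone and 3 held the Y-linked genes alone. In db/db, Xist alone was held by fl/fl db/db 1, KO db/db 1 and KO db/db 3. The Y-linked genes alone were held by fl/fl db/db 2, fl/fl db/db 3 and KO db/db 2.

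**Figure D2:**
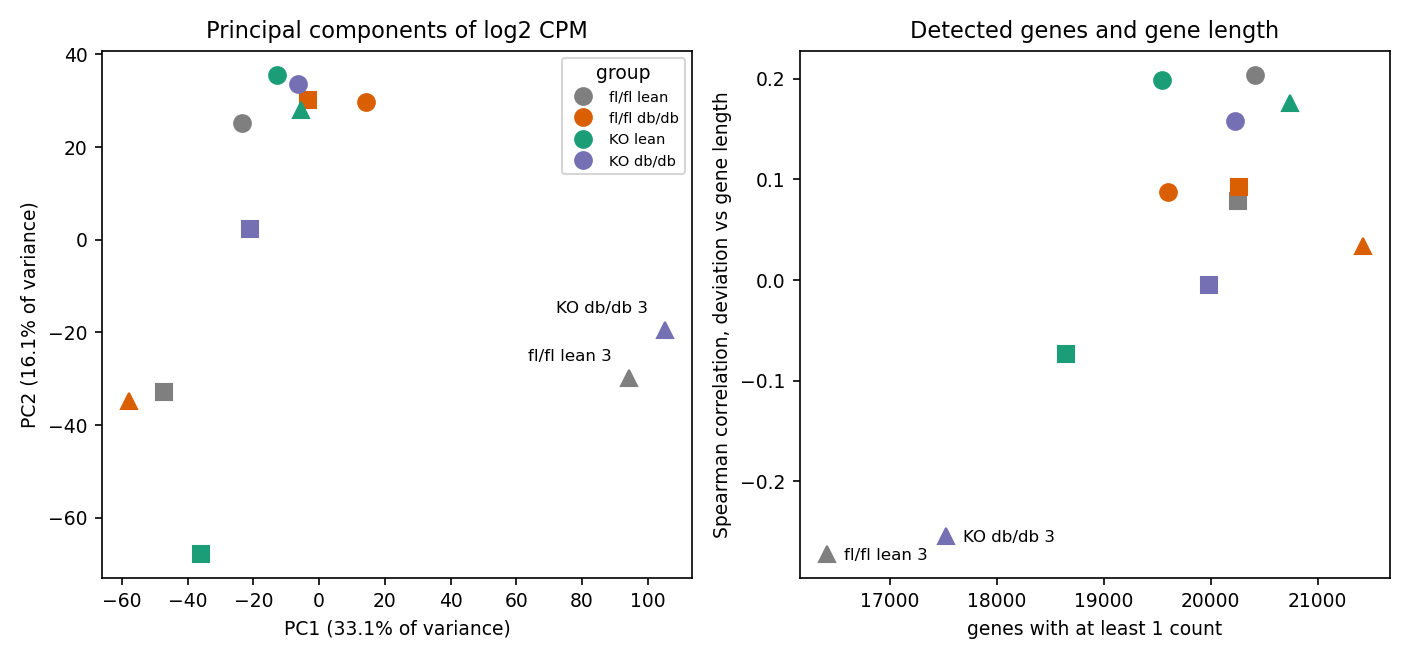
Left, the first and second principal components of log2 CPM in the 12 libraries, with the share of variance in percent on each axis. Right, genes with at least 1 count against the Spearman correlation of gene deviation with gene length; colours mark groups and symbols replicates, and fl/fl lean 3 and KO db/db 3 lie apart in both panels.

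**Figure D3:**
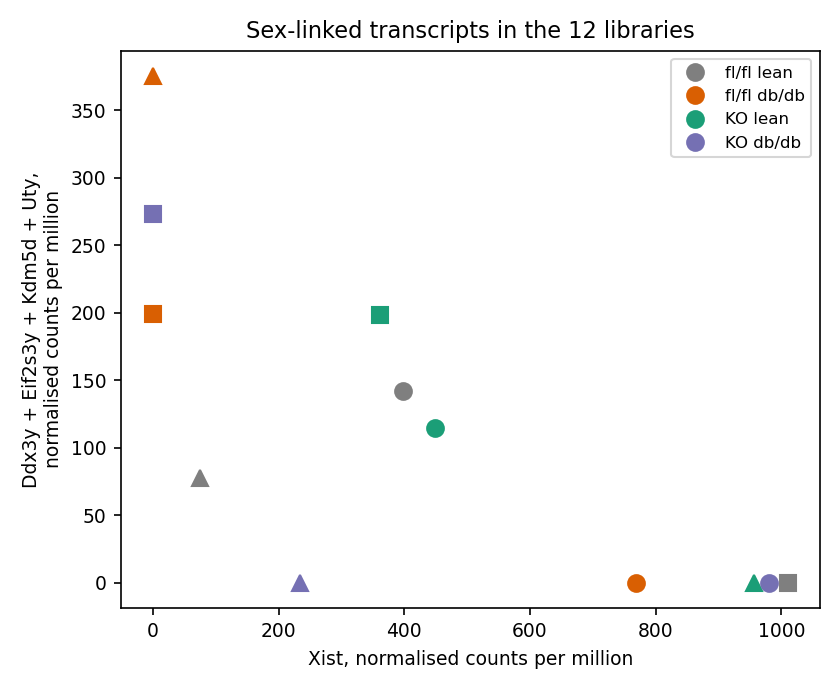
Xist against the sum of Ddx3y, Eif2s3y, Kdm5d and Uty, in CPM, in the 12 libraries; colours mark groups and symbols replicates. The 4 libraries away from both axes are fl/fl lean 1 and 3 and KO lean 1 and 2.

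In fl/fl fibroblasts, the comparison of db/db with lean asks what the diabetic background changes while Smad3 is intact. Genes of lipogenesis and sterol synthesis were lower in db/db, at 19 of 21 tested members (median log2 fold change -0.61; camera adjusted p = 1.45e-08, but adjusted p = 0.897 with an estimated correlation). Srebf2, which switches on sterol synthesis, was at 124 ± 19.2 CPM in db/db and 207 ± 29.4 in lean (log2 fold change -0.73, SE 0.29). Matricellular proteins, secreted proteins that modulate the matrix, were higher at 14 of 18 members (median 0.40; camera adjusted p = 0.00697, and adjusted p = 0.897 with an estimated correlation). Among them Thbs4 was at 74.0 ± 45.0 CPM in db/db and 28.0 ± 5.06 in lean, and Spp1, osteopontin, at 6.99 ± 5.27 and 0.448 ± 0.413. Contractile and myofibroblast genes were lower at 14 of 17 members (median -0.26, camera adjusted p = 0.00419), with the collagen-binding integrin subunit Itga11 at 82.0 ± 12.9 and 128 ± 16.0 CPM and Actn1 at 42.9 ± 4.89 and 61.0 ± 10.7. With an estimated correlation the contractile list had an adjusted p = 0.897. Its score, the mean deviation of its members on the log2 scale, was 0.56 in fl/fl lean 2, which held 64.3 CPM of mesothelial markers and 18123 CPM of mitochondrially encoded genes, and -0.40 to -0.11 in the other 5 libraries. The lipogenesis score was also highest in fl/fl lean 2 (0.39), and without that library the list still passed (camera adjusted p = 0.000932).

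Stress genes of fl/fl db/db fibroblasts were also lower: 16 of 20 members of the unfolded protein and integrated stress response (median -0.23) and 19 of 22 immediate-early and dissociation stress genes (median -0.20), with a camera adjusted p = 0.0308 for each, and adjusted p = 0.897 with an estimated correlation. Sdf2l1, a chaperone component of the endoplasmic reticulum, was at 12.8 ± 4.22 CPM in db/db and 24.3 ± 23.4 in lean, Egr1 at 3956 ± 646 and 5140 ± 2219, and Ier2 at 520 ± 20.3 and 768 ± 351. The collagen list did not pass (median 0.17, camera adjusted p = 0.328), and Col1a2 was at 3494 ± 252 and 3111 ± 210 CPM. No single gene passed with edgeR: 0 of 15890 were called, 274 had an unadjusted p under 0.05 where 5% would be 794, DESeq2 called 3 genes and voom 0. No list member passed over all genes or adjusted over the list alone. With 1 library left out, the matricellular call was lost without fl/fl lean 1 (median 0.39, adjusted p = 0.168) or fl/fl db/db 2 (0.27, adjusted p = 0.112). The contractile call was lost without fl/fl lean 2 (median -0.09, adjusted p = 0.373) or fl/fl db/db 3 (-0.20, adjusted p = 0.0825). The immediate-early call was lost without fl/fl lean 1 (median 0.02, adjusted p = 0.760), fl/fl lean 2 (-0.12, adjusted p = 0.147), fl/fl db/db 1 (0.06, adjusted p = 0.594) or fl/fl db/db 2 (-0.04, adjusted p = 0.402). The unfolded protein call was lost without fl/fl lean 2 (median -0.20, adjusted p = 0.153), fl/fl db/db 1 (-0.20, adjusted p = 0.0567), fl/fl db/db 2 (-0.12, adjusted p = 0.344) or fl/fl lean 3, which stood apart (0.05, adjusted p = 0.833). Egr1 had a log2 fold change of 0.03 without fl/fl lean 1, and Sdf2l1 one of 0.25 without fl/fl lean 3. That of Ier2 was -0.56, with -0.32 without fl/fl lean 1 and -0.90 without fl/fl lean 2. That of Spp1 was 3.94 with all libraries, 3.31 without fl/fl db/db 2 and 4.64 without fl/fl lean 3.

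**Figure D4:**
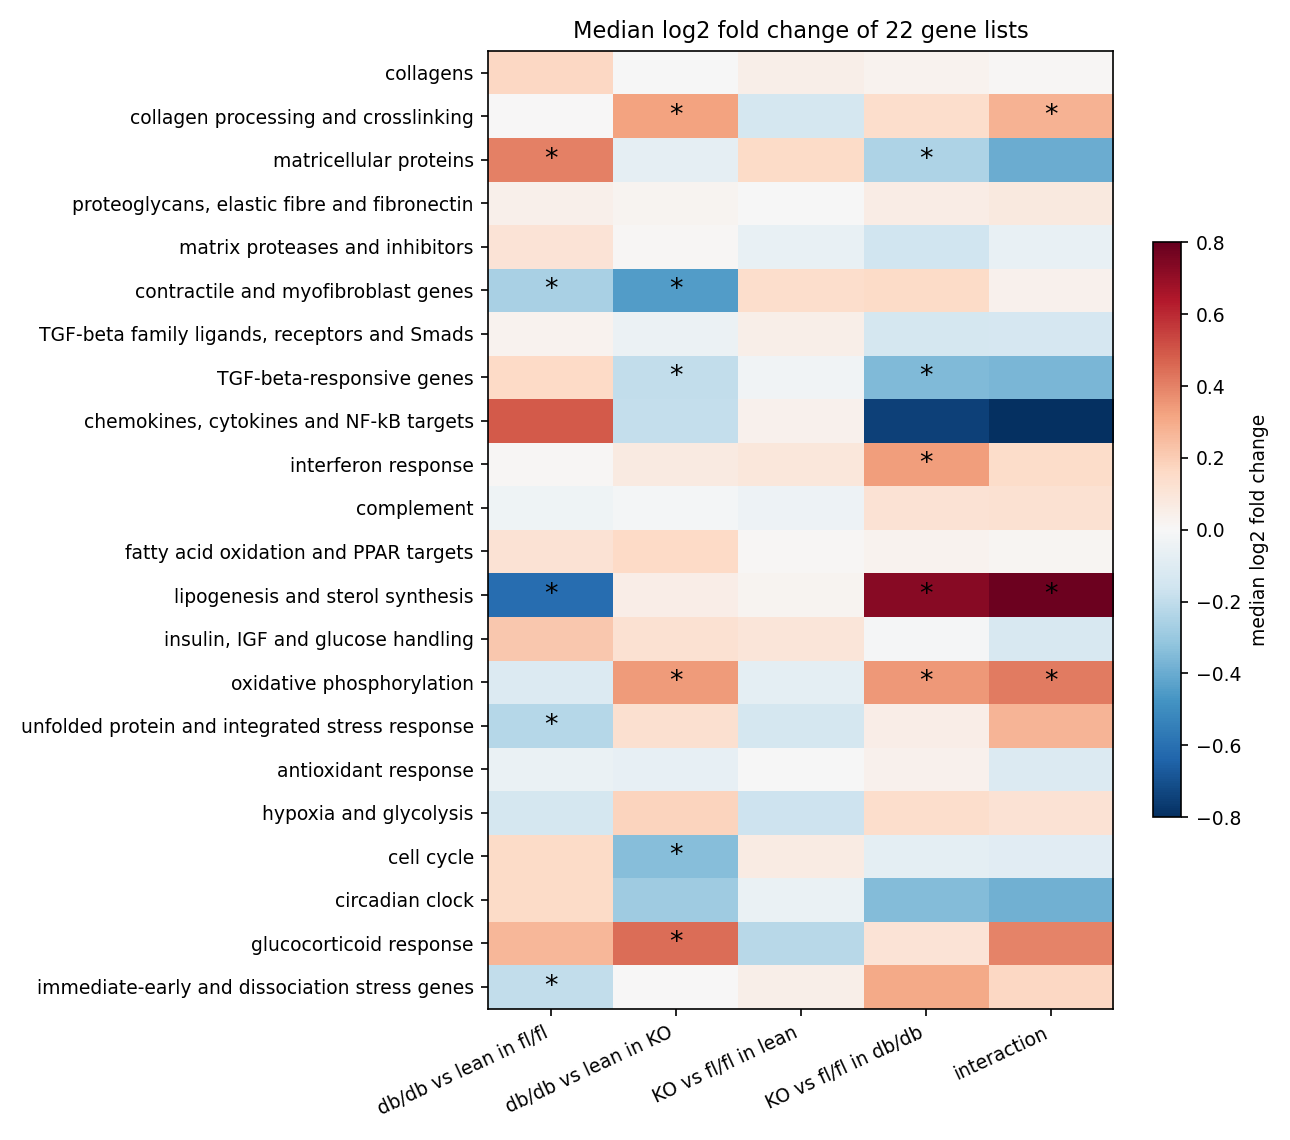
Median log2 fold change of the tested members of 22 gene lists in the 4 simple contrasts and the interaction, as a colour scale. An asterisk marks an adjusted p under 0.05 by camera with a preset correlation of 0.01; 19 of the tests have one, and with an estimated correlation 0 have.

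In db/db fibroblasts, the comparison of KO-labelled with fl/fl libraries asks what the loss of Smad3 changes under diabetes. Lipogenesis and sterol synthesis genes were higher in the KO-labelled libraries at 17 of 21 members (median log2 fold change 0.73; camera adjusted p = 6.88e-09, but adjusted p = 0.732 with an estimated correlation), among them Lss at 16.2 ± 4.68 against 9.4 ± 2.36 CPM and the sterol carrier Stard4 at 21.1 ± 13 against 8.43 ± 1.54. The score of this list was 0.79 in KO db/db 1 and 0.06 in KO db/db 3, while KO db/db 2 (-0.35) lay within the fl/fl db/db libraries (-0.55 to -0.32). KO db/db 1 and KO db/db 3 held Xist alone and KO db/db 2 the Y-linked genes alone. Among the fl/fl db/db libraries, fl/fl db/db 1 (-0.35) held Xist alone. The lists were not tested with the Y-linked covariate. Without KO db/db 1 the adjusted p was 0.0395 and the median 0.46, and the log2 fold changes of Lss and Stard4 were 0.52 and 0.75, against 0.78 and 1.32 with it. Matricellular proteins were lower at 11 of 18 members (median -0.25; camera adjusted p = 0.0157, and adjusted p = 0.732 with an estimated correlation). The thrombospondin Thbs4 was at 13.6 ± 5.33 CPM in the KO-labelled and 74.0 ± 45.0 in the fl/fl libraries, where fl/fl db/db 3 was at 22.2. Its log2 fold change of -2.45 (SE 0.57) passed adjusted over the list alone (edgeR adjusted p = 0.0188) and not over all genes (0.990), with -2.88 to -1.98 and adjusted p from 5.77e-13 to 1 over the alternatives. Cilp was at 192 ± 88.4 and 401 ± 145 CPM, and Postn, periostin, at 326 ± 228 and 671 ± 165, while Cyr61 of the same list was at 1434 ± 215 and 840 ± 177. The log2 fold change of Postn was -1.04, with -1.71 without KO db/db 1 and -0.64 without KO db/db 3, which stood apart. The summed CPM of 8 markers of activated fibroblasts, which include Thbs4, Cilp and Postn, was 808 ± 397 in the KO-labelled and 1561 ± 460 in the fl/fl db/db libraries, with overlapping ranges. It was lowest in KO db/db 3 (386 CPM), without which the KO-labelled mean was 1020 CPM.

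TGF-beta-responsive genes were lower in the KO-labelled db/db libraries at 19 of 23 members (median -0.35; camera adjusted p = 0.00532, and adjusted p = 0.732 with an estimated correlation), with Klf10 at 45.9 ± 2.93 against 67.6 ± 14.7 CPM and Pmepa1, an inhibitor of TGF-beta signalling, at 236 ± 59.5 against 330 ± 56.3. Interferon response genes were higher at 18 of 23 members (median 0.34; camera adjusted p = 8.00e-04, and adjusted p = 0.732 with an estimated correlation), with Usp18 at 12.7 ± 2.81 against 6.66 ± 1.35 CPM and Ifi27l2a at 276 ± 195 against 136 ± 23.2. The log2 fold change of Ifi27l2a was 1.02, and 0.28 without KO db/db 3, which stood apart. Oxidative phosphorylation genes were higher at 25 of 28 members (median 0.35; camera adjusted p = 5.05e-05, but adjusted p = 0.925 with an estimated correlation), with Uqcrc1 at 140 ± 68.9 against 90.6 ± 7.18 CPM and Ndufb9 at 25.1 ± 6.45 against 15.9 ± 2.78. Collagens did not pass as a list (median 0.03, camera adjusted p = 0.923), with Col3a1 at 4889 ± 1709 against 3868 ± 386 CPM and Col8a1 at 375 ± 153 against 657 ± 149. With edgeR 0 genes were called and 375 had an unadjusted p under 0.05, while DESeq2 called 3 and voom 2, with Gpt2 called by both. Of the list members, 0 passed over all genes and 1, Thbs4, adjusted over the list alone. The oxidative phosphorylation call rested on KO db/db 3, which stood apart (median 0.02, adjusted p = 0.978 without it) and had the highest cardiomyocyte markers, at 65.9 CPM. The score of this list was highest in KO db/db 3 (0.69) and in fl/fl lean 3 (0.47), where the cardiomyocyte markers were at 23.4 CPM. Without KO db/db 3 the log2 fold changes of Uqcrc1, Col3a1 and Col8a1 were 0.15, 0.06 and -0.53, against 0.63, 0.34 and -0.81 with it, and that of Col3a1 was 0.57 without KO db/db 2. The matricellular call was lost without KO db/db 3 with a median about as large (-0.21, adjusted p = 0.359), and without fl/fl db/db 2 with a smaller median (-0.11, adjusted p = 0.131). The TGF-beta-responsive call was lost without KO db/db 3 (median -0.18, adjusted p = 0.195) or fl/fl db/db 3 (-0.12, adjusted p = 0.0923), and the interferon call without fl/fl db/db 2 (0.17, adjusted p = 0.120).

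In lean fibroblasts, KO-labelled and fl/fl libraries differed least. Gpt2, a mitochondrial alanine aminotransferase, was at 30.3 ± 5.31 CPM in the KO-labelled and 10.3 ± 1.12 in the fl/fl libraries (log2 fold change 1.55, SE 0.28), and no list passed (lowest camera adjusted p = 0.0996, for collagen processing and crosslinking). With edgeR 0 genes were called and 98 had an unadjusted p under 0.05, while DESeq2 and voom each called 1 gene, Gpt2. Of the list members, 0 passed over all genes and 0 adjusted over the list alone. With 1 library left out, lists were called in this comparison: without KO lean 2, which held the mesothelial markers, there were 10, without fl/fl lean 1 there were 4, and without fl/fl lean 2, fl/fl lean 3 or KO lean 1 there were 2 each.

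Averaged over lean and db/db, 1 gene was called between KO-labelled and fl/fl libraries. Gpt2 (chromosome 8, 85492576 to 85527560) was higher in all 6 KO-labelled libraries than in any of the 6 fl/fl libraries, at 29.5 ± 2.79 CPM in KO-labelled db/db and 8.70 ± 3.16 in fl/fl db/db. Its averaged log2 fold change was 1.66 (SE 0.20; edgeR adjusted p = 0.0207), and it is the gene with the smallest p, so this size is likely to be too large. DESeq2 and voom called the same gene and no other. With edgeR 167 genes had an unadjusted p under 0.05. Over the alternatives the log2 fold change stayed between 1.23 and 1.77 with adjusted p from 2.33e-10 to 0.160, and the gene was called in 10 of 23, including 4 of the 12 with a library left out. It was not called without fl/fl lean 1 (adjusted p = 0.112), fl/fl lean 2 (0.112), fl/fl lean 3 (0.0551), fl/fl db/db 1 (0.0874), KO lean 1 (0.111), KO lean 3 (0.116), KO db/db 1 (0.0720) or KO db/db 2 (0.0701). Gpt2 was chosen after its values were seen.

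Within KO-labelled fibroblasts, the comparison of db/db with lean asks which diabetic changes appear under the KO label. Collagen processing and crosslinking genes were higher at 18 of 20 members (median log2 fold change 0.32; camera adjusted p = 0.00222, but adjusted p = 0.973 with an estimated correlation), with the procollagen protease Adamts14 at 24.4 ± 8.92 against 12.5 ± 0.669 CPM and P4ha3, a subunit of collagen prolyl hydroxylase, at 4.01 ± 0.607 against 1.34 ± 0.117. Glucocorticoid-response genes were higher at 10 of 14 members (median 0.45; camera adjusted p = 0.00222, and adjusted p = 0.973 with an estimated correlation), with Fkbp5 at 95.2 ± 26.3 against 47.8 ± 6.20 CPM and Tsc22d3 at 449 ± 265 against 116 ± 34.7. Both of these passed adjusted over the list alone (edgeR adjusted p = 0.0391 each) and not over all genes (0.951). Over all groups Tsc22d3 was highest in the libraries that stood apart, KO db/db 3 (700 CPM) and fl/fl lean 3 (519 CPM). Its log2 fold change here was 1.48 to 2.34 with a library left out. Oxidative phosphorylation genes were higher at 26 of 28 members (median 0.34; camera adjusted p = 5.09e-04, and adjusted p = 0.973 with an estimated correlation), with Uqcrc1 at 140 ± 68.9 against 87.2 ± 2.84 CPM and Atp5c1 at 131 ± 51.9 against 89.1 ± 11. The log2 fold changes of Uqcrc1 and Atp5c1 were 0.68 and 0.56, and 0.20 each without KO db/db 3, which also held 65.9 CPM of cardiomyocyte markers. Contractile genes were lower at 14 of 17 members (median -0.45; camera adjusted p = 0.0270, and adjusted p = 0.973 with an estimated correlation), with the smooth muscle leiomodin Lmod1 at 2.74 ± 1.38 against 7.96 ± 6.40 CPM and Actn1 at 44.7 ± 12.3 against 63.7 ± 16.9. The contractile score was highest in KO lean 2 (0.99, against -0.52 to 0.11 in the other 5), which held 220 CPM of mesothelial markers and 20249 CPM of mitochondrially encoded genes and had Lmod1 at 15.3 CPM. The log2 fold changes of Lmod1 and Actn1 were -1.54 and -0.51, and -0.66 and -0.29 without KO lean 2. The mean log2(CPM + 1) of the pericyte and smooth muscle markers was also higher in KO lean 2 (4.85) and fl/fl lean 2 (4.79) than in the other 10 libraries (3.32 to 4.36), although their summed CPM was not. TGF-beta-responsive genes were lower at 18 of 23 members (median -0.20; camera adjusted p = 0.0270, and adjusted p = 0.973 with an estimated correlation), with the matrix protein Tgfbi at 190 ± 36.9 against 382 ± 31.8 CPM. Cell cycle genes were lower at 14 of 21 members (median -0.34; camera adjusted p = 0.0411, and adjusted p = 0.973 with an estimated correlation), where Cenpf was at 0.200 ± 0.0354 against 1.33 ± 0.244 CPM.

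In the proteoglycan and elastic fibre list, Fbn2, a fibrillin of elastic fibres, was at 36.4 ± 15.2 CPM in KO-labelled db/db and 8.44 ± 4.76 in KO-labelled lean, and passed adjusted over the list alone (log2 fold change 2.11, SE 0.50, edgeR adjusted p = 0.0283). Of the matricellular genes, whose list did not pass, Thbs2 was at 1170 ± 348 against 660 ± 64.1 CPM, Wisp2 at 279 ± 248 against 84.3 ± 31.6 and Thbs4 at 13.6 ± 5.33 against 31.2 ± 21.2. The log2 fold change of Wisp2 was 1.73, and 0.72 without KO db/db 2, and that of Thbs4 was -1.20, and -0.50 without KO lean 2. With edgeR 0 genes were called and 614 had an unadjusted p under 0.05, the most of the simple contrasts, while DESeq2 called 11 and voom 3, with Lepr and Spock2 called by both. Of the list members, 0 passed over all genes and 3 adjusted over the list alone. Without KO db/db 3, which stood apart, the calls of oxidative phosphorylation (median 0.02, adjusted p = 0.907), collagen processing (0.11, adjusted p = 0.327), TGF-beta-responsive (-0.15, adjusted p = 0.401) and cell cycle genes (-0.28, adjusted p = 0.0731) were lost. Without KO lean 2 those of contractile (median -0.05, adjusted p = 0.737), TGF-beta-responsive (-0.15, adjusted p = 0.284) and cell cycle genes (-0.11, adjusted p = 0.287) were lost. Without KO db/db 2 those of contractile (median -0.22, adjusted p = 0.669), glucocorticoid-response (0.20, adjusted p = 0.325) and cell cycle genes (-0.13, adjusted p = 0.353) were lost. The collagen processing call was also lost without KO lean 3 (median 0.23, adjusted p = 0.0622), and the cell cycle call without KO lean 3 (-0.35, adjusted p = 0.156) or KO db/db 1 (-0.25, adjusted p = 0.109).

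Averaged over both genotypes, the genes that differed most between db/db and lean libraries missed the threshold with edgeR. Besides Lepr, Gria1, a subunit of a glutamate receptor, had a log2 fold change of 2.59 (SE 0.36; edgeR adjusted p = 0.0562), at 15.7 ± 6.73 CPM in fl/fl db/db and 1.91 ± 0.521 in fl/fl lean and at 13.2 ± 6.25 and 3.00 ± 1.95 CPM in the KO-labelled groups. Its log2 fold change within the KO-labelled groups was 2.14, and 2.81 without KO lean 1. Spock2, a matrix proteoglycan, was at 244 ± 39.2 against 131 ± 10.6 CPM in fl/fl and 280 ± 53.5 against 133 ± 21.1 in KO-labelled libraries (log2 fold change 0.98, SE 0.15; edgeR adjusted p = 0.0779). Adjusted over the list alone, 6 members passed: the matrix genes Fbn2 (1.88), Eln (0.72) and Adamts14 (0.73) and the glucocorticoid target Fkbp5 (0.99) rose, and Tgfbi (-0.92) and the complement regulator Cd55 (-0.66) fell. Their edgeR p-values adjusted over the list alone were 0.00369, 0.0337, 0.0321, 0.00542, 0.00718 and 0.0422 in that order. Over all genes 0 of these 6 passed with edgeR. These 6 genes, Gria1 and Spock2 were chosen after their values were seen. With edgeR 0 genes were called and 624 had an unadjusted p under 0.05, against 34 called with DESeq2 and 55 with voom, of which 17 were the same genes. Lepr, Gria1, Spock2, Fbn2, Fkbp5 and Tgfbi were among these 17, and Eln, Adamts14 and Cd55 were not. Without both libraries that stood apart, edgeR called 5 genes, Lepr and Fkbp5 among them. With 1 library left out it called 6 genes without fl/fl lean 3, 4 without KO db/db 3 and 1 without KO lean 1, and 0 otherwise.

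The interaction asks whether the difference between KO-labelled and fl/fl libraries depends on db/db. Oxidative phosphorylation genes (median 0.41, 26 of 28 members positive), lipogenesis and sterol synthesis genes (median 0.79, 18 of 21) and collagen processing genes (median 0.28, 17 of 20) passed with camera at adjusted p = 1.26e-04, 1.11e-04 and 0.0429, but at adjusted p = 0.906 each with an estimated correlation. With edgeR 0 genes were called and 219 had an unadjusted p under 0.05, while DESeq2 and voom called 0. Of the list members, 0 passed over all genes and 0 adjusted over the list alone. Without both libraries that stood apart, the median of oxidative phosphorylation reversed to -0.19 and passed the other way (camera adjusted p = 0.0341), and that of collagen processing reversed to -0.09 (0.936), while lipogenesis passed at 0.66 (5.07e-05). The oxidative phosphorylation call was lost without fl/fl lean 3 (median 0.09, adjusted p = 0.273) or KO db/db 3 (0.09, adjusted p = 0.278) alone, and the lipogenesis call without KO db/db 1 (0.36, adjusted p = 0.135). The collagen processing call was lost without any one of fl/fl lean 2 (median 0.34, adjusted p = 0.114), fl/fl lean 3 (0.08, adjusted p = 0.273), fl/fl db/db 1 (0.32, adjusted p = 0.140), KO lean 1 (0.18, adjusted p = 0.147), KO lean 3 (0.22, adjusted p = 0.228) or KO db/db 3 (0.08, adjusted p = 0.299).

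The db/db effects of both genotypes, which share no library, correlated weakly across genes (r = 0.136; genes are not independent replicates), and 44.9% of genes had the same sign. An unadjusted p under 0.05 in both was found for 66 genes, where independent lists would share 10.6 in either direction. Of the 66, 61 went the same way, Lepr, Gria1 and Tgfbi among them. Other groupings of the libraries did not exclude chance for these 61 genes. The KO effects in db/db and in lean had r = -0.044, and 38.6% of genes had the same sign. An unadjusted p under 0.05 in both was found for 4 genes, where independent lists would share 2.31 in either direction, and 1 of the 4 went the same way. Without both libraries that stood apart these correlations were 0.306 and 0.082. With 1 library left out they ranged from -0.089 to 0.316 and from -0.194 to 0.142. Of the 22 lists, 11 were called in none of the 4 simple contrasts and the interaction, with a lowest camera adjusted p of 0.218. These were collagens (lowest adjusted p = 0.328), proteoglycans and elastic fibre (0.406), matrix proteases (0.413), TGF-beta family ligands, receptors and Smads (0.283), chemokines and NF-kB targets (0.340) and complement (0.582). The others were fatty acid oxidation (0.287), insulin and glucose handling (0.218), antioxidant response (0.406), hypoxia and glycolysis (0.218) and the circadian clock (0.283). The chemokine list had medians from -0.81 to 0.49 over these tests.

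Of the genes that db/db changed in fl/fl, 0 moved back with the KO label, since edgeR called 0 in either contrast. The log2 fold changes of these contrasts, which share the 3 fl/fl db/db libraries, had r = -0.448 across genes against -0.503 in simulated unchanged groups. Their covariance was -0.115 against -0.165 (SD 0.0042 over 20 simulations). Opposite signs were found for 69.3% of genes against 66.7% in the simulation, so the measures did not all lie on the same side of it.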

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

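The tests on the libraries that stood apart, on lipogenesis, on the splits, and on Gpt2 with the Y-linked covariate and its neighbours were chosen only after the results were seen; the test on the paralog Gpt was not. The effects of 3 gene lists differed between groups by the interaction test, with camera at a preset correlation. These were oxidative phosphorylation (median 0.41, adjusted p = 1.26e-04), lipogenesis and sterol synthesis (median 0.79, adjusted p = 1.11e-04) and collagen processing (median 0.28, adjusted p = 0.0429). Each had an adjusted p = 0.906 with an estimated correlation. Without fl/fl lean 3 and KO db/db 3, oxidative phosphorylation reversed to a median of -0.19 that passed the other way (adjusted p = 0.0341) and collagen processing to -0.09 (0.936), while lipogenesis kept its direction (0.66, adjusted p = 5.07e-05).

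Libraries fl/fl lean 3 and KO db/db 3 stand apart from the others on the first principal component. The tables argue against fewer counted reads, since 0 of the 2 had a total below the lowest of the others. They also argue against more cells of another type in both. Of 9 marker lists of other cell types, 0 were higher in both than in all other libraries. That test cannot see fewer such cells. Macrophage (5.58 and 5.50 CPM), Schwann (38.8 and 30.4) and epicardial markers (0.867 and 2.18) were lowest in fl/fl lean 3 and KO db/db 3, while the other lists were not. Fibroblast markers were highest there in summed CPM (89949 and 104780), so a difference in cell composition is not excluded. In mean log2(CPM + 1), fibroblast markers were higher in KO db/db 2 (11.79) than in fl/fl lean 3 (11.70). On that scale macrophage markers were lower in fl/fl db/db 1 (0.359) than in KO db/db 3 (0.408). Schwann and epicardial markers stayed lowest in fl/fl lean 3 and KO db/db 3 on both scales. Lower complexity or RNA quality stays open and may be the source: 2 of the 2 had fewer detected genes and a lower length correlation than all others. No biological explanation was tested, since the libraries belong to different groups.

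Lipogenesis and sterol synthesis genes were lower in fl/fl db/db than in both fl/fl lean and KO-labelled db/db. The libraries that stand apart do not set this, since without them the higher of the adjusted p-values was 5.98e-05. A single library does not set the difference from fl/fl lean (highest adjusted p = 0.000932 with a library left out). For KO-labelled db/db it stays open: without KO db/db 1 the adjusted p was 0.0395, and the interaction was lost (median 0.36, adjusted p = 0.135). Both differences use the same fl/fl db/db libraries, so low values in those alone would give both without an effect of Smad3. The fl/fl and KO-labelled db/db libraries also differed in which held Xist or Y-linked transcripts. This list was not tested with the Y-linked covariate. An effect of Smad3 under diabetes is a candidate explanation that was not tested, and with an estimated correlation the adjusted p-values were 0.897 and 0.732.

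Gpt2 was higher in the KO-labelled libraries. The tables argue against the mix of sexes, since with the Y-linked covariate its log2 fold change was 1.63, against 1.66 (SE 0.20), although the call ended (adjusted p = 0.0703; 2.33e-10 to 0.160 over the alternatives), for a reason not tested. They argue against reads shared with the paralog Gpt, whose log2 fold change was -0.20 (SE 0.32). Of 39 tested neighbours within 1 Mb, 0 were higher at an unadjusted p under 0.05. Over all genes only 74 of 15890 were, so this count cannot tell whether the whole region changed by a smaller amount. An effect of the KO label stays open as a hypothesis, and so does chance. At least 1 gene was called in 6 of 100 splits of the libraries, the real one among them.

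All counts of splits given here include the real grouping. For the 3 against 3 comparisons the 10 splits are too few for a share under 0.05. With edgeR, 0 genes were called in each real split, which all 10 of 10 splits must reach; the highest other called 0 for db/db against lean in fl/fl, 1 for KO against fl/fl in db/db, 0 for KO against fl/fl in lean and 0 for db/db against lean in KO. Lists called were 5 for db/db in fl/fl (8 of 10 splits gave as many, highest other 11), 5 for KO in db/db (7 of 10, highest 14), 0 for KO in lean (10 of 10, highest 15) and 6 for db/db in KO (8 of 10, highest 11). For the lists of the interaction chance is not excluded: 83 of 100 splits called at least the real 3 lists (highest other 12). Nor is it for the averaged effect of KO, with 1 gene (6 of 100, highest other 340), or for the 61 genes shared by the db/db effects (14 of 100, highest other 547). The interaction and the averaged effect of db/db had 0 genes, a count that 100 of 100 splits must reach, so these splits say nothing about chance (highest other 1 and 187). Splits that call many genes point to a structure of the samples. With both libraries that stand apart on the same side, the median count at an unadjusted p under 0.05 was 726.5 for KO and 695 for db/db, against 315 and 236.5 with them on opposite sides. The real groups had them on opposite sides, with 167 for KO and 624 for db/db. The splits that gave 340 and 547 had them on the same side, so the shares over 100 splits pool unlike splits. With them on opposite sides, the genes shared by the db/db effects still reached 197 in another split and 91 in a further one. They stayed below the real 61 in the rest of these 50 splits.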

How the results depend on the processing

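Leaving out both libraries that stood apart and the Y-linked covariate were chosen only after the results were seen. RLE size factors kept all 19 list calls, and the stricter filter and the replicate block 18 each, the cell cycle list being lost (adjusted p = 0.0587 and 0.0670). With an estimated correlation or fry, 0 lists were called in total and in each contrast. Of the results for named genes under other settings 572 kept direction and side of the threshold, 48 newly passed, 5 no longer passed and 2 reversed. Of the 57 named-gene results only Gpt2 for averaged KO was called in the main fit. For the others, keeping the side of the threshold meant only staying uncalled. Examples near 0 had mostly been passed over, so the kept directions do not measure robustness. Among all list members the rule takes for called lists, 35 of 846 values under other settings and 39 of 462 with a library left out turned sign. These values came from 77 gene results. Of the 77, 19 turned sign under some other setting and 26 with some library left out.

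Genes called, in the order db/db in fl/fl, KO in db/db, KO in lean, db/db in KO, interaction, averaged KO and averaged db/db, were 66, 119, 17, 193, 39, 25 and 192 with no filter, where the prior degrees of freedom became infinite against 5.01. DESeq2 gave 3, 3, 1, 11, 0, 1 and 34, and voom 0, 2, 1, 3, 0, 1 and 55. Log2(FPKM + 1) on all genes gave 2, 2, 1 and 0 for the simple contrasts and 0 for averaged KO, as did log2(FPKM + 0.1), the replicate block and the Y-linked covariate for averaged KO. The block gave 3 for averaged db/db; 6 of 18 pairs of the same number correlated over 0.1, so the numbers do not clearly pair libraries. The 6 libraries compared alone gave 1 for KO in db/db and 1 for db/db in KO. Except where stated, the cause was not tested.

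Without both libraries that stood apart, genes called were 1 for KO in db/db, 1 for db/db in KO, 0 for averaged KO and 5 for averaged db/db, and lists 3 for KO in db/db, 2 for KO in lean and 2 for db/db in KO. The medians of the unfolded protein list in fl/fl (0.043), and for the interaction of collagen processing (-0.085) and oxidative phosphorylation (-0.19, adjusted p = 0.0341) reversed. Correlations of the db/db effects and of the KO effects were 0.306 and 0.082. Sdf2l1 in fl/fl reversed to 0.25 there and to 0.21 with voom.

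With 1 library left out, genes called ranged from 0 to 1 for averaged KO and 0 to 6 for averaged db/db, and were 0 in the others. List calls ranged from 11 to 35 in total, 3 to 7 for db/db in fl/fl, 3 to 9 for KO in db/db, 0 to 10 for KO in lean, 2 to 9 for db/db in KO and 1 to 10 for the interaction. The correlation of the db/db effects ranged from -0.089 to 0.316 and of the KO effects from -0.194 to 0.142. In fl/fl the median of the unfolded protein list ranged from -0.45 to 0.047, the log2 fold change of Sdf2l1 from -1.31 to 0.25 and that of Egr1 from -0.60 to 0.026. Of 2-fold changes edgeR recovered 0% to 7% in the simulated simple contrasts and interaction, so changes of that size would mostly be missed.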

Other observations

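The test on pooled libraries was chosen only after the result was seen. Xist and Y-linked transcripts were both above 5 CPM in 4 of 6 lean and 0 of 6 db/db libraries (Fisher exact test, two-sided p = 0.0606). A candidate explanation is that these 4 libraries were pooled from animals of both sexes. Then the Xist level as a share of that in libraries with Xist alone, added to the same share for Y-linked genes, would lie within the range of single libraries. It did in 3 of the 4, at 0.931, 0.887 and 1.09 for fl/fl lean 1, KO lean 1 and KO lean 2, against 0.705 to 1.33, and not in fl/fl lean 3 (0.355). The range was redefined after its first value was seen: with KO db/db 3 (0.252) in it, 4 of 4 lay within. Libraries with mixed reads from another sample would give the same values, so pooling cannot be told apart from that.

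Among genes with an unadjusted p under 0.05 in both db/db against lean in fl/fl and KO against fl/fl in db/db, 16 were higher and then lower and 32 lower and then higher. Independent lists would share 1.74 and 1.49, but these contrasts share 3 libraries. Genes whose 3 libraries did not overlap between groups made up 5.93% for db/db in fl/fl, 8.87% for KO in db/db, 3.88% for KO in lean and 10.8% for db/db in KO, where chance gives 10%.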
